A study of Hordeum vulgare with 12 samples.

How the data were processed

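Gene expression was measured by RNA-seq in the basal centimetre of barley shoots, with leaf 1 removed, from 7-day-old plants of the mutants blf13 and nal1 and the wild types Bonus and Sebastian. Per the labels, each genotype has 3 biological replicates, each a pool of 6 plants, total RNA was extracted with TRIzol and libraries were made with a NEBNext Ultra RNA kit. That kit does not mark strand, and reads fell on the sense strand of genes in 50.5% to 50.7% of cases. The deposited files hold, for each library, raw read counts per gene in the layout of STAR's gene count output, and STAR 2.7.3a is named in the submitters' processing notes. The genome build, trimming and filters are not given in the sources used here; the gene IDs are those of the barley MorexV3 annotation (HORVU.MOREX.r3). In this output, a read that maps to several places or overlaps several genes is counted for no gene, so near-identical gene copies are undercounted, and reads of a gene and an antisense neighbour cannot be told apart.

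The column of counts made without regard to strand was used, for 81687 gene IDs. The 4 summary lines of each file, for reads that were unmapped, multimapping, outside genes or ambiguous, were kept out of library sizes and tests. They held 15.7% to 37.9% of the reads of a library. The highest share was in blf13 replicate 2, with 29.8% unmapped and 4.01% multimapping reads, and the other libraries had 10.3% to 17.8% unmapped reads. Counts in genes came to 14831979 to 62995658 per library. Pairs of replicates differed by 3.98 to 11.8 times the sampling noise in a chi-square statistic per degree of freedom, so no library was present in duplicate.

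The reference table of barley genes matched 0 of the 81687 IDs and gives no products. The lists of gene groups fixed before the data were examined, and the barley gene for NARROW LEAF1 itself, were therefore not analysed here, and expression of the mutated gene could not serve as a check of the labels. Chromosomes were read from the IDs, and position is given as rank in ID order, with no coordinates. At most 2 genes that rose and 2 that fell are named per comparison, taken before the data were examined as those with the largest log2 fold change among genes with an adjusted p under 0.05, no overlap between the 3 mutant and 3 wild-type libraries and at least 1 CPM in the higher group. For genes changed in both mutants, the smallest larger adjusted p decided. HORVU.MOREX.r3.2HG0190650 was added after its values were seen.

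Counts were tested with edgeR 4.0.16 in R 4.3.3 (TMM normalization, filterByExpr, quasi-likelihood F test), with 1 coefficient per genotype fitted to all 12 libraries so that they share an estimate of the spread. The contrasts were blf13 minus Bonus, nal1 minus Sebastian, Sebastian minus Bonus, and the difference between both mutant effects (blf13 minus Bonus, less nal1 minus Sebastian) as the interaction. Genes with a Benjamini-Hochberg adjusted p under 0.05 count as changed, and 22437 genes were tested. CPM values were computed here from the counts with TMM library sizes. Standard errors of log2 fold changes were derived from the F statistic. A gene with no count in a genotype was given a lower bound of its fold, against a floor of 3 counts summed over the 3 libraries. With 1 count, the ratio has its 95% counting interval. For genes with no count, that interval reaches closer to no change than the floor bound, and its limit is given beside the bound. Bounds and intervals cover counting error only. The classes of 2-fold and 8-fold use fitted fold changes, which depend on the prior count for genes near 0. Overlaps were tested with Fisher's exact test across genes, and expected overlaps are the product of the list sizes over the number of genes tested. Neither mutant comparison shares a library with the other. Positions were tested with Fisher's exact test per chromosome and with 10000 shuffles of gene order. Sharing of 8-fold changes with Sebastian was set against 10000 draws from the 200 tested genes nearest in Bonus CPM to each gene, 8-fold changed genes left out.

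Whether equal replicate numbers pair libraries is not stated in the labels and was checked from the data, as the correlation of deviations from the genotype means. It was 0.219, 0.315 and 0.213 for numbers 1, 2 and 3 of blf13 and Bonus, so these numbers were taken to pair the libraries. For nal1 and Sebastian the values were −0.100, −0.041 and 0.110, and for Sebastian and Bonus they were −0.035, −0.015 and −0.0096. The main fit holds no term for the pairing of blf13 and Bonus, so its counts ignore that pairing. Counts from fits with a replicate block are given beside them. The exact tests of overlap and of chromosomes were not repeated with a block.

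On simulated counts with the means, dispersions and library sizes of these libraries and 200 changed genes per comparison among 22437, 50 of each fold size, the test recovered 36.0%, 68.0%, 92.0% and 100.0% of genes changed 1.5-, 2-, 4- and 8-fold between blf13 and Bonus, with 3.90% false calls. For nal1 and Sebastian it recovered 46.0%, 70.0%, 92.0% and 90.0%, with 5.10% false calls. Of 60 genes simulated with opposite changes, 44 were found as such and 0 as changed in the same direction. The simulated libraries were drawn independently, with no cultivar difference and no trend with expression level. They lacked the shared deviation of same-numbered blf13 and Bonus libraries, and held fewer changed genes than the 2590 called in nal1. The recovery and false-call rates hold for that setting and do not give those of the real comparisons.

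Alternatives fixed before the data were examined were DESeq2 1.42.0, median-of-ratios size factors (RLE), no low-count filter or a stricter one (over 1 CPM in at least 3 libraries), the 6 libraries of a comparison alone, replicate number as a block, an adjusted p under 0.01, a test against a fold of 1.5 (glmTreat), shorter runs of 50 genes and leaving out each library. Added after the data were seen were a replicate block within each cultivar, cyclic loess normalization (limma 3.58.1), leaving out replicate 2 of both blf13 and Bonus, the pair with the most multimapping reads, and the test against a fold of 1.5 for genes changed in both mutants.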

Results

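RNA-seq gene counts were analysed for 12 libraries from the basal centimetre of the shoot of 7-day-old barley (Hordeum vulgare), a piece that contains the shoot apex and the growing bases of the young leaves after removal of leaf 1. The 4 genotypes were the mutant blf13 and the cultivar Bonus in whose background it stands, and the mutant nal1 and its wild type Sebastian. There were 3 biological replicates per genotype, each a pool of 6 plants. Per the series title, blf13 is a gain-of-function mutation in the barley counterpart of rice NARROW LEAF1, a regulator of leaf growth, and goes with wider leaves. Reads counted in genes ranged from 14831979 in nal1 replicate 1 to 62995658 in Sebastian replicate 3, with a median of 27400641. Between 27803 and 32097 genes had at least 1 count in a library, and 22437 genes were tested in every comparison. The files give gene IDs without names, so genes are reported by ID, by expression level, by chromosome and by their direction in the mutants.

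Libraries differed more between the cultivar backgrounds than between a mutant and its wild type. Log2 CPM of libraries of the same genotype correlated across genes with r of 0.985 to 0.994, those of a mutant and its own wild type with 0.980 to 0.989, and those of different cultivar backgrounds with 0.907 to 0.941. The first principal component held 71.3% of the variance and placed all 6 Bonus-background libraries on one side and all 6 Sebastian-background libraries on the other. Genes are not independent replicates, and these correlations describe the libraries only. Any separate growth or handling of the backgrounds cannot be told apart from cultivar, as the labels name no batch. Reads of both were counted in MorexV3 genes, and how well each cultivar matches that annotation was not tested.

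The comparison of blf13 with Bonus asks which transcripts differ between the mutant line and its background cultivar. Any other genetic difference between the line and Bonus is part of this contrast, along with the allele. The 4 genes named by the fixed rule were each close to a complete presence or absence. On chromosome 5H, HORVU.MOREX.r3.5HG0444260 had no count in Bonus and 738 counts in blf13, at 7.70 ± 0.68 CPM (SD, n = 3). Against the floor of 3 counts this was at least 174-fold higher, and the 95% counting interval began at 141-fold. HORVU.MOREX.r3.5HG0455680, also on 5H, had no count in Bonus and 231 in blf13, at 2.39 ± 0.20 CPM (SD, n = 3). By the floor it was at least 54.6-fold higher, with a counting interval from 44.0-fold. In the other direction, HORVU.MOREX.r3.5HG0474210 on 5H had 3584 counts in Bonus, at 53.1 ± 8.73 CPM (SD, n = 3), and 1 count in blf13, a blf13 to Bonus ratio of 0.000198 with a 95% counting interval of 5.01e-06 to 0.00110. HORVU.MOREX.r3.3HG0310020 on 3H had 355 counts in Bonus, at 5.26 ± 0.81 CPM (SD, n = 3), and none in blf13. By the floor it was at least 167-fold lower, and the 95% counting interval of the blf13 to Bonus ratio reached 0.00741. The edgeR quasi-likelihood adjusted p was 2.50e-05, 0.000247, 5.61e-09 and 9.37e-05 for these genes in the order given. Over all tested genes, 716 (3.19%) changed at an adjusted p under 0.05, 271 of them higher and 445 lower in blf13. Most changes were small, with a median absolute log2 fold change of 0.48. Changes of 2-fold or more were mostly increases, in 121 genes against 55 decreases, and 32 genes rose and 19 fell by 8-fold or more. With cyclic loess normalization, which removes a trend of the fold change with expression level, 228 genes were higher and 225 lower, so that 50.3% of the changed genes were higher in place of 37.8%. Same-numbered blf13 and Bonus libraries deviated together, which the main fit does not take into account. The count of lower genes was 286 with a replicate block and 193 with that block set within each cultivar, against 208 and 200 higher genes. These counts rest on single libraries: without blf13 replicate 1, 2 or 3 they were 121, 114 and 579 higher and 72, 87 and 940 lower genes, and without Bonus replicate 1, 2 or 3 they were 135, 111 and 507 higher and 156, 85 and 1240 lower genes. With DESeq2 they were 408 and 965, and without the low-count filter 1095 and 969. They were 105 and 52 when fitted to the 6 Bonus-background libraries alone, and 80 and 39 without replicate 2 of both genotypes, of which the blf13 library had the most unmapped reads (29.8%).

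The comparison of nal1 with Sebastian asks the same of the second mutant. The largest changes lay on chromosome 2H. A pair of genes with consecutive ranks there, HORVU.MOREX.r3.2HG0125800 and HORVU.MOREX.r3.2HG0125790, had no count in Sebastian. HORVU.MOREX.r3.2HG0125800 had 892 counts in nal1, at 13.05 ± 1.095 CPM (SD, n = 3), and HORVU.MOREX.r3.2HG0125790 had 80 counts, at 1.19 ± 0.16 CPM (SD, n = 3). Against the floor of 3 counts they were at least 502-fold and 45.02-fold higher, and their 95% counting intervals began at 407-fold and 35.8-fold. HORVU.MOREX.r3.2HG0212120 fell from 451 counts in Sebastian, at 3.91 ± 0.24 CPM (SD, n = 3), to 1 count in nal1, a ratio of 0.00374 with a 95% counting interval of 9.46e-05 to 0.0210. HORVU.MOREX.r3.2HG0203150 fell from 9.27 ± 1.16 to 0.147 ± 0.085 CPM (SD, n = 3 each), a log2 fold change of −5.92 (SE 0.35). The edgeR adjusted p of these genes, in the order given, was 7.60e-06, 0.00135, 1.47e-08 and 9.59e-07. The gene with the smallest p, singled out after its values were seen, was HORVU.MOREX.r3.2HG0190650, which stood at 177 ± 4.05 CPM in Sebastian and 34.7 ± 1.49 CPM in nal1 (SD, n = 3 each), a log2 fold change of −2.35 (SE 0.06, edgeR adjusted p = 3.38e-11). In all, 2590 genes (11.5%) changed, 1374 higher and 1216 lower in nal1, with a median absolute log2 fold change of 0.44. Of the changes of 2-fold or more, 368 were increases and 95 decreases, and 9 genes rose and 7 fell by 8-fold or more. Without nal1 replicate 2 or 3 the counts were 530 and 530 higher and 434 and 484 lower genes, and without Sebastian replicate 2 or 3 they were 494 and 306 higher and 375 and 341 lower genes. Without the low-count filter 2115 genes were higher.

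Whether the same genes changed in both mutant lines was examined by setting the changed genes of both comparisons side by side, which share no library. More of the shared genes moved the same way than in opposite directions, and the genes named next are of the opposite kind. HORVU.MOREX.r3.1HG0095330 rose in blf13 from 22.2 ± 2.20 to 91.2 ± 6.86 CPM (log2 fold change 2.04, SE 0.09) and fell in nal1 from 17.04 ± 1.67 to 5.06 ± 0.16 CPM (−1.74, SE 0.11). HORVU.MOREX.r3.5HG0433990 rose in blf13 from 17.1 ± 1.68 to 33.1 ± 0.54 CPM (0.96, SE 0.07) and fell in nal1 from 18.6 ± 0.74 to 3.30 ± 0.09 CPM (−2.50, SE 0.09), each value a mean with its SD over n = 3 libraries. The difference between both effects, tested as an interaction with edgeR, had a log2 size of 3.77 for HORVU.MOREX.r3.1HG0095330 (SE 0.14, adjusted p = 2.81e-09) and 3.46 for HORVU.MOREX.r3.5HG0433990 (SE 0.12, adjusted p = 1.70e-09). Of 175 genes changed in both mutants, 97 moved the same way and 78 (44.6%) in opposite ways. This share depended on the setting, with 152 of 432 genes opposite with DESeq2 and 62 of 88 with loess normalization. In 34 cases a gene was higher in blf13 and lower in nal1, where the sizes of both lists give 14.7 (Fisher's exact test across genes, two-sided, adjusted p = 9.86e-06). The reverse held for 44 genes against 27.3 (adjusted p = 0.00242 by the same exact test). Lower in both were 79 genes against 24.1 (adjusted p = 2.22e-20, exact), and 18 were higher in both against 16.6 (adjusted p = 0.701, exact). By list sizes pooled over expression levels, the excess was largest for genes lower in both, at 3.28 times, against 2.31 and 1.61 times for the opposite classes. This order did not hold with loess normalization. There the ratio was 4.39 for genes higher in blf13 and lower in nal1, 2.29 for genes lower in both and 2.19 for the reverse change. The list sizes, pooled over expression levels, give about as many opposite as same-direction genes, and the opposite share of 44.6% was not above that. Direction also followed expression level, in the same way in both mutants. This comparison therefore does not show whether the share was raised among genes of like level. These expectations and tests take genes as independent and equally likely to be called. The changed share instead rose from 1.38% under 1 CPM to 8.70% over 100 CPM in blf13, and from 5.22% to 23.5% in nal1. Over 100 CPM, 172 genes were lower and 8 higher in blf13, and 423 were lower and 64 higher in nal1. Level therefore puts more genes in the class lower in both than the list sizes give, so part of that excess can come from it. For the opposite classes the shared direction acts the other way, and expected counts within levels were not computed. The p-values take no account of level. The overlaps rest on single libraries, and the 34 genes became 22 and 16 without blf13 replicate 1 or 2, 19 and 22 without Bonus replicate 1 or 2, 18 without nal1 replicate 3, and 22 and 18 without Sebastian replicate 2 or 3. The 79 genes lower in both became 12, 15 and 123 without blf13 replicate 1, 2 or 3, 30, 17 and 252 without Bonus replicate 1, 2 or 3, 19 and 15 without nal1 replicate 2 or 3, and 14 and 12 without Sebastian replicate 2 or 3, and the 78 genes with opposite changes became 33, 22, 144, 34, 32, 164, 47, 35, 39 and 32 in the same order. The 44 genes lower in blf13 and higher in nal1 became 11, 6 and 106 without blf13 replicate 1, 2 or 3, 15, 10 and 122 without Bonus replicate 1, 2 or 3, 24, 24 and 17 without nal1 replicate 1, 2 or 3, and 27, 17 and 14 without Sebastian replicate 1, 2 or 3. With a replicate block within each cultivar, 116 genes were changed in both. Of these, 40 were lower in both, 40 higher in blf13 and lower in nal1, and 29 had the reverse change. Tested with edgeR's glmTreat against a fold of 1.5 in both mutants, 3 genes were changed in both, 2 of them higher in blf13 and lower in nal1, none with the reverse change and none lower in both.

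Level and size of change varied between these 4 classes, a description without a test. The 34 genes higher in blf13 and lower in nal1 had a median level of 10.4 CPM and median absolute log2 fold changes of 0.86 in blf13 and 0.92 in nal1. The 79 genes lower in both had a median level of 281 CPM, 56 of them lay over 100 CPM, and their median absolute changes were 0.29 and 0.25. The 44 genes lower in blf13 and higher in nal1 stood between these, at 24.3 CPM with changes of 0.49 and 0.44, and the 18 genes higher in both, at 5.45 CPM with 0.83 and 0.61, lay near the 34. An example of the genes lower in both is HORVU.MOREX.r3.6HG0552800, at 396 ± 19.8 CPM in blf13 against 508 ± 35.0 in Bonus and 498 ± 8.41 in nal1 against 624 ± 27.1 in Sebastian (SD, n = 3 each), with log2 fold changes of −0.36 and −0.32. Another is HORVU.MOREX.r3.3HG0252240, with −0.32 and −0.37. In blf13, HORVU.MOREX.r3.6HG0552800 and HORVU.MOREX.r3.3HG0252240 did not pass the edgeR test with the 6 libraries alone (adjusted p = 0.0641 and 0.0733) or without the replicate 2 pair (0.0551 and 0.0684), and neither passed it in either mutant against a fold of 1.5. With loess normalization their log2 fold changes were −0.23 and −0.19 in blf13 and −0.21 and −0.25 in nal1. Of 14 genes changed 2-fold or more in both mutants, 11 moved in opposite ways. With loess normalization the lists were shorter. Then 37 genes were higher in blf13 and lower in nal1, 28 of them among the 34, which was 4.39 times the 8.42 that the list sizes give (2.31 times before). The 44 genes with the reverse change became 25, 20 of them among the 44, or 2.19 times the 11.4 given by list sizes (1.61 before). The 79 genes lower in both became 19, 17 of them among the 79, or 2.29 times the 8.31 given by list sizes (3.28 before). The 18 genes higher in both became 7, or 0.604 times the 11.6 given by list sizes (1.08 before). That class was not followed through the other settings. Across all tested genes the log2 fold changes of both mutants were nearly uncorrelated (Pearson r = −0.018, Spearman rho = 0.121), a value that moved between −0.152 without blf13 replicate 1 and 0.161 without blf13 replicate 2.

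The interaction test over all genes found 1171 genes (5.22%) whose response differed between the mutants, 411 with the higher fold change in blf13 and 760 with the higher fold change in nal1. Of these, 569 were changed in nal1 alone, 245 in blf13 alone, 81 in both and 276 in neither. The 1171 include genes with almost no counts in 1 cultivar background, where a response could not be seen, and these were not counted apart. An example is HORVU.MOREX.r3.5HG0474210, at 0 CPM in Sebastian and 0.0105 CPM in nal1 (edgeR interaction adjusted p = 0.0326). HORVU.MOREX.r3.2HG0190650, lowered in nal1, had 179 ± 3.91 CPM in blf13 and 188 ± 10.2 CPM in Bonus (SD, n = 3 each; edgeR adjusted p = 0.447), and the interaction had a log2 size of 2.28 (SE 0.07, adjusted p = 1.70e-09). The number of genes was 574 without blf13 replicate 2, 702 without Bonus replicate 2, 758 without nal1 replicate 3, 754 and 549 without Sebastian replicate 2 and 3, and 410 without the replicate 2 pair of blf13 and Bonus. Without the low-count filter it was 2210.

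**Figure D1:**
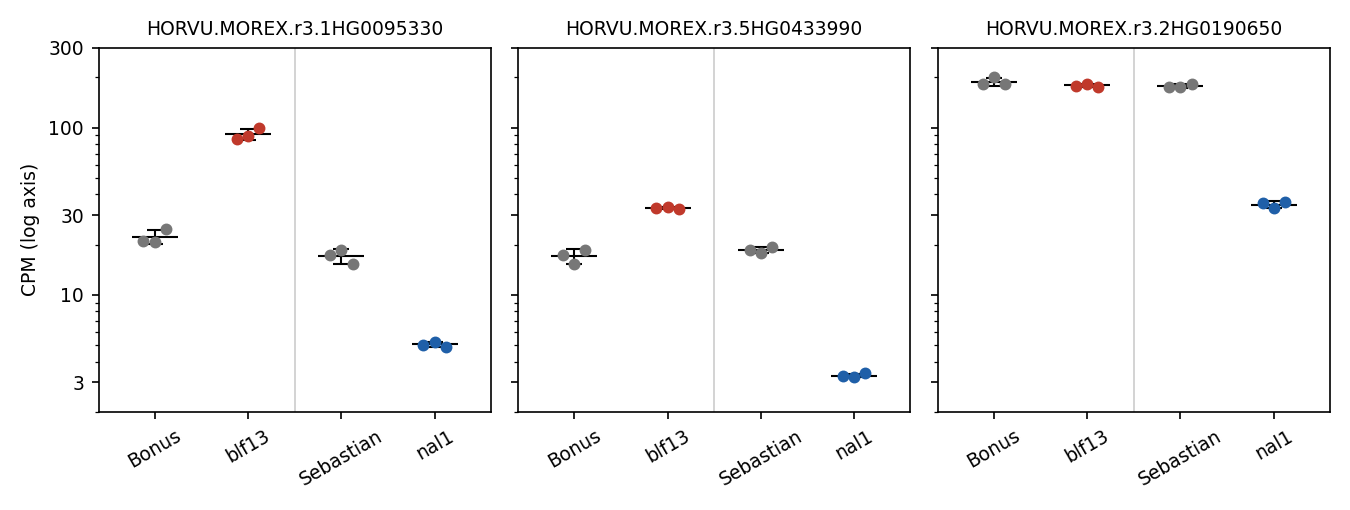
Expression in CPM (log axis) of 3 genes in every library of Bonus, blf13, Sebastian and nal1; points are libraries, the long dash is the mean and the bar the SD (n = 3). HORVU.MOREX.r3.1HG0095330 and HORVU.MOREX.r3.5HG0433990 lie above Bonus in blf13 and below Sebastian in nal1, whereas HORVU.MOREX.r3.2HG0190650 is lower in nal1, at 34.7 CPM, than in the other genotypes, at 177 to 188 CPM.

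**Figure D2:**
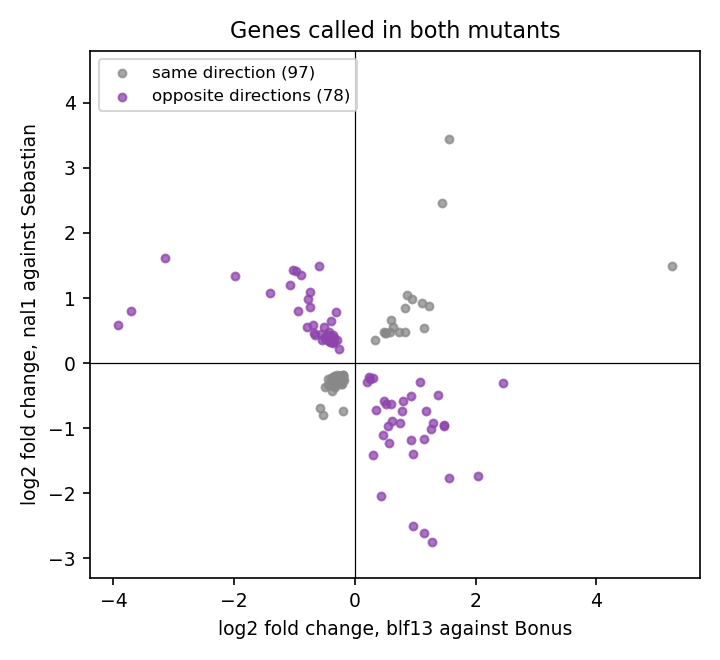
Log2 fold change in blf13 against Bonus (horizontal axis) and in nal1 against Sebastian (vertical axis) for the 175 genes changed in both; each point is a gene. The 79 genes lower in both lie near 0, and many of the 78 genes with opposite directions lie further out, as do some of the 18 genes higher in both.

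Direction followed expression level in both mutants. Among genes with a mean over 100 CPM, 8 were higher and 172 lower in blf13, and 64 were higher and 423 lower in nal1, of 2068 tested. Among genes of 1 to 10 CPM the balance was the other way, with 142 higher and 65 lower in blf13 and 623 higher and 137 lower in nal1, of 7694 tested. Over all tested genes, changed or not, the median log2 fold change of genes over 100 CPM was −0.10 in blf13 and −0.10 in nal1, and that of genes of 1 to 10 CPM was 0.06 and 0.10. The same medians between the wild types, Sebastian against Bonus, were −0.0043 and 0.00052. With loess normalization the genes over 100 CPM were 20 higher and 38 lower in blf13, and 163 higher and 126 lower in nal1. Tested against a fold of 1.5, 33.3% of the changed genes over 100 CPM were lower in nal1, in place of 86.9%. That test left 77 changed genes at all levels in nal1, so its share can rest on few genes. These level classes were chosen after the data were seen.

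**Figure D3:**
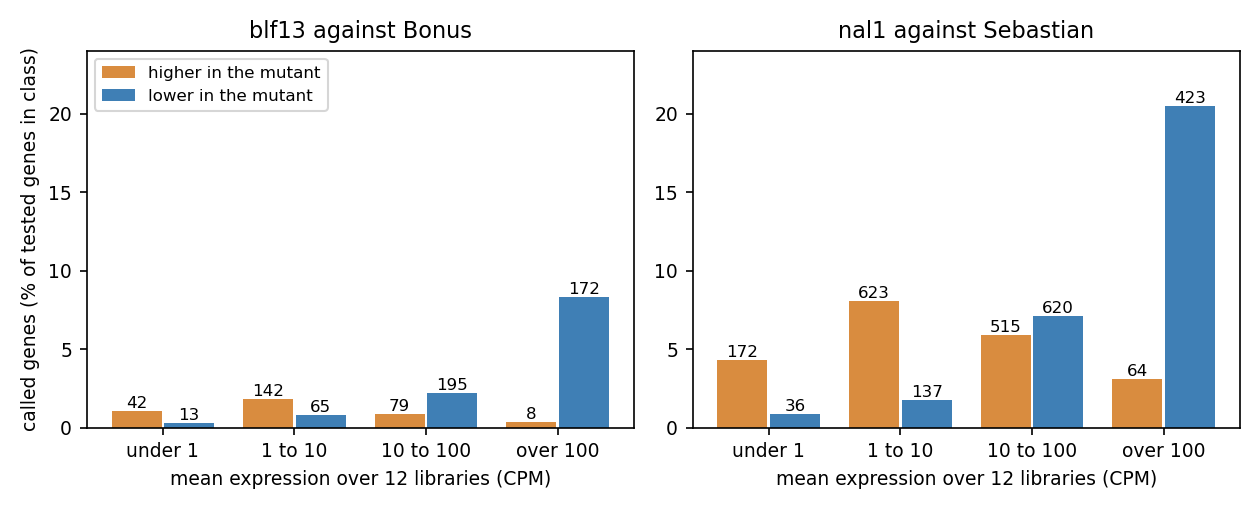
Share of tested genes that were higher or lower in each mutant (vertical axis, % of tested genes in the class) by mean expression over the 12 libraries (horizontal axis, CPM); the number of genes stands above each bar. Lower genes dominate over 100 CPM (172 against 8 in blf13, 423 against 64 in nal1) and higher genes dominate under 10 CPM.

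By chromosome, the changed genes as a whole were spread much as the tested genes were. Of 14 Fisher's exact tests, 7 per mutant, 1 passed the adjustment, with 374 of the 2590 genes changed in nal1 on 4H (14.4%, against 12.5% of tested genes; odds ratio 1.22, adjusted p = 0.0194), and with loess normalization 0 of 14 passed. The fullest run of 100 consecutive tested genes held 10 changed genes in blf13 and 24 in nal1, which shuffled gene orders equalled with a permutation p of 0.263 and 0.0754; with loess normalization the p for nal1 was 0.0350, with the stricter filter 0.222 and with runs of 50 genes 0.415. Fold classes were tested in the same way after the data were seen. Among changes of 2-fold or more no chromosome passed, with 39 of 176 genes on 5H in blf13 and 96 of 463 on 2H in nal1 (Fisher's exact adjusted p = 0.158 each). Changes of 8-fold or more were less evenly placed. In blf13, 19 of 51 such genes lay on 5H (37.3%, against 15.9% of tested genes; Fisher's exact odds ratio 3.15, 95% interval 1.68 to 5.73, adjusted p = 0.00250), 10 of them higher and 9 lower. In nal1, 8 of 16 lay on 2H (against 16.6% of tested genes; odds ratio 5.02, 95% interval 1.64 to 15.3, exact adjusted p = 0.0148), 4 higher and 4 lower.

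**Figure D4:**
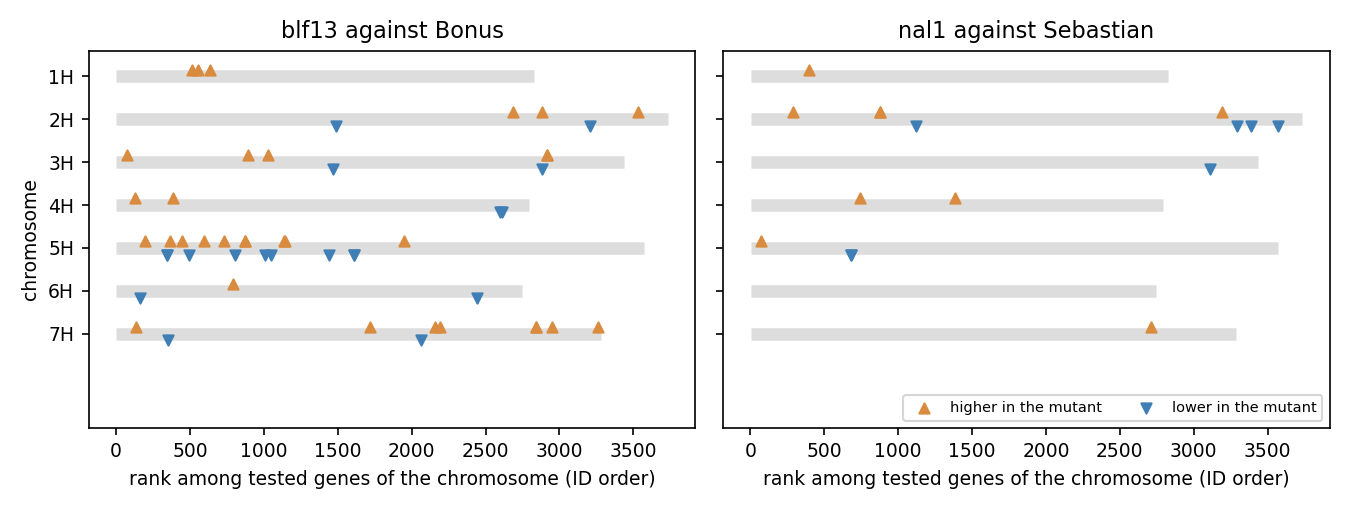
Genes changed by 8-fold or more in blf13 (left) and nal1 (right) by chromosome (vertical axis) and by rank among the tested genes of that chromosome in ID order (horizontal axis); grey bars span the tested genes, upward triangles mark genes higher and downward triangles genes lower in the mutant. On 5H in blf13, 18 of the 19 marks rank below the middle of the chromosome's tested genes, and 8 of 16 marks in nal1 lie on 2H.

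Sebastian and Bonus, the wild types, were compared to give a scale for the mutant effects. Between them 3939 genes (17.6%) differed by edgeR, 1893 higher and 2046 lower in Sebastian, with a median absolute log2 fold change of 0.72. Differences of 8-fold or more were common here, in 434 genes higher and 394 lower in Sebastian, against 51 genes in blf13 and 16 in nal1. By a stricter measure of presence, at least 1 CPM in all 3 libraries of one genotype and under 0.1 CPM in all 3 of the other, 151 genes were on in Bonus and off in Sebastian and 146 the reverse. By that measure 7 genes were on in Bonus and off in blf13, 7 the reverse, 1 was on in Sebastian and off in nal1 and 2 the reverse, the last 3 being HORVU.MOREX.r3.2HG0212120, HORVU.MOREX.r3.2HG0125790 and HORVU.MOREX.r3.2HG0125800. These limits were also set after the data were seen.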

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

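The counts of regrouped libraries were planned before their results were seen, as was the comparison of gains in weak and silent genes; the other tests below, namely the regroupings that part the replicate pairs, level trend removal, tilt, depth, the deleted stretch and states shared with Sebastian, were chosen after the patterns were seen. Groups of 3 libraries are too small for a test of outlying samples.

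The effects of the mutants differed in 1171 genes by the interaction test of edgeR. In 60 regroupings of the libraries within each cultivar, the real one included, only the real one gave as many. The highest of the others gave 611. So high a count was rare in these draws, but they cannot exclude chance assignment of libraries. Regroupings that mix genotypes put the genotype difference into the spread, which lowers their counts. The 60 draws also took no account of the replicate numbers that pair blf13 and Bonus, and did not include the exchange of labels given next. Of the 80 regroupings that part all 3 of these pairs, 2 gave as many (2.50%), the real one and the one with the labels of nal1 and Sebastian exchanged, which gave 2756; the highest of the others was 1024. The count goes with effects that follow the labels. Since the exchanged labels gave more genes, it does not by itself show that the effects are opposed. For single comparisons 10 splits of 6 libraries are too few for a share under 0.05. There 1 of 10 splits, the real one, gave as many genes in each case. The real value was 716 for blf13 against Bonus, 2590 for nal1 against Sebastian and 3939 for Sebastian against Bonus, and the highest of the other splits was 0 each time. For blf13 and Bonus, whose numbers pair the libraries, 4 of the splits part all 3 pairs, and the other 3 of these gave 0 genes as well, as did the splits that keep a pair together.

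Among these, 78 genes changed in opposite directions in the mutants; their difference also passed its test, which the choice of genes past both tests with opposite signs makes nearly certain. Of the named genes, HORVU.MOREX.r3.1HG0095330 differed by 3.77 on the log2 scale, HORVU.MOREX.r3.5HG0433990 by 3.46 and HORVU.MOREX.r3.2HG0190650, changed in nal1 and not past the threshold in blf13, by 2.28. The 34 genes higher in blf13 and lower in nal1 were equalled in 1 of 60 regroupings, the real one, and the highest other count was 0; no split that mixed the genotypes of a cultivar called a gene there, so this count bears on the calls and not on their opposite directions. With the trend of fold change with expression level removed, the count was 37, which is 4.39 times what the list sizes give. That trend ran the same way in both mutants, so it would not place genes in this opposite class. Its removal could therefore hardly lower the ratio, and the 4.39 times is no test of the trend as a cause. The list sizes take every gene as equally likely to be called, so the ratio also holds any excess from genes that are easier to call. The 44 genes with the reverse change became 25, or 2.19 times what the list sizes give against 1.61 times before, and the 79 genes lower in both became 19, or 2.29 times against 3.28 before. Opposite effects of a gain-of-function allele and the other mutant allele remain an untested biological hypothesis, and genetic differences between Bonus and Sebastian stay open as well.

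Abundant genes were lower and weak genes higher in both mutants. One scaling factor per library moves all levels alike, yet the tilt, the median log2 CPM of genes over 100 CPM minus that of genes of 1 to 10 CPM, differed by −0.159 for blf13 minus Bonus and by −0.188 for nal1 minus Sebastian, with all 3 mutant libraries below all 3 wild-type libraries in each cultivar (exact permutation test within cultivars, two-sided, p = 0.005, or 0.0125 over the 160 regroupings that part the replicate pairs of blf13 and Bonus). The tilt measures the same pattern that prompted it, so this p is no independent evidence. Sequencing depth went opposite ways, at 1.31 times Bonus in blf13 and 0.568 times Sebastian in nal1. A uniform background of reads from outside genes would raise silent genes as much as weak ones, but genes under 0.1 CPM gained at most 0.0293 of what genes of 1 to 10 CPM gained. The silent genes were chosen by their mean over all 12 libraries, mutants included. That choice limits the gain they could show, so the ratio alone cannot settle this explanation. A different mix of tissues or growth stages in the mutant samples, RNA quality and a length or GC bias stay open, the last because no gene lengths or sequences were used here.

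Large changes in blf13 were in excess on 5H. The tables argue against a single deleted stretch, since 96.0% of the 1092 other tested genes ranked between the first and last 5H gene lost in blf13 lay within 2-fold of Bonus. Segments that differ between cultivars stay open. Of 7 genes on in Bonus and off in blf13, 4 were also off in Sebastian, 2 of them on 5H, against 151 of 17302 genes on in Bonus (0.873%; Fisher's exact p = 1.91e-07). Of the 19 genes on any chromosome that were 8-fold or more lower in blf13, 9 were also 8-fold or more lower in Sebastian, where drawing genes of like level in Bonus gives 0.460 (permutation p = 0.000100). On 5H this held for 2 of 9, against 0.205 (permutation p = 0.0158), which leaves most of the 9 unaccounted for. Genes that rose have no fair background, since a gene silent in Bonus was tested only if expressed elsewhere, and 41.2% of such genes were on in Sebastian. Of the 32 genes 8-fold or more higher in blf13, 6 stood so in Sebastian, 1 of 10 on 5H, and 1 of 7 gained genes was on in Sebastian. Between the wild types, 5H held the most genes on in one and off in the other, 30 of 151 on in Bonus only and 31 of 146 on in Sebastian only. It also held 15.9% of tested genes, and these counts were not tested against that share. Neighbouring genes are not independent, and 3 of the 7, among them a neighbouring pair on 5H, were on in Sebastian. Introgression from another parent, further mutations in the line and effects of blf13 itself could not be separated with these counts.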

How the results depend on the processing

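The replicate block within each cultivar, the loess normalization and the joint removal of replicate 2 of blf13 and Bonus were chosen after the data were seen, as were the alternatives for the count of genes lower in blf13 and higher in nal1 and for the share of lower genes over 100 CPM. The other settings were planned. The 18 results for named genes were recomputed in 287 alternatives and kept their direction in 286; HORVU.MOREX.r3.2HG0190650 in blf13, which did not pass the test in any, turned from −0.07 to 0.0089 with loess normalization. HORVU.MOREX.r3.6HG0552800 and HORVU.MOREX.r3.3HG0252240 no longer passed the test for blf13 in 3 settings (the 6 libraries alone, without the replicate 2 pair, against a fold of 1.5) and for nal1 against a fold of 1.5. DESeq2 gave no adjusted p for HORVU.MOREX.r3.2HG0125790 in nal1. Unless the setting itself tests fewer libraries or sets a stricter threshold, the cause of a change in the counts below was not tested.

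The counts are given against 271 higher and 445 lower genes in blf13, 1374 higher and 1216 lower in nal1, 3939 between the wild types, 1171 for the interaction, 175 changed in both mutants, 78 of them in opposite directions, 34 higher in blf13 and lower in nal1, 44 with the reverse change, and 79 lower in both. DESeq2 gave 408 and 965 for blf13, 432 in both mutants, 152 opposite, 107 with the reverse change and 241 lower in both. Without the low-count filter there were 1095 and 969 for blf13, 2115 higher in nal1, 2210 for the interaction, 649 in both, 307 opposite, 102 higher in blf13 and lower in nal1, 205 with the reverse change, and 134 lower in both. The 6 Bonus-background libraries alone gave 105 and 52 for blf13. At an adjusted p under 0.01 there were 91 and 63 for blf13, 318 and 294 for nal1, 2431 between the wild types, 350 for the interaction, 20 in both, 11 opposite, 8 higher in blf13 and lower in nal1, 3 with the reverse change, and 5 lower in both. Against a fold of 1.5 there were 54 and 28 for blf13, 40 and 37 for nal1, 1379 between the wild types, 140 for the interaction and, added after the data were seen, 3 in both, 2 opposite, 2 higher in blf13 and lower in nal1, 0 with the reverse change and 0 lower in both. Loess normalization gave 225 lower genes in blf13, 88 in both, 25 with the reverse change and 19 lower in both, and 0 chromosomes with an excess of changed genes. RLE normalization and the stricter filter moved no count by over 1.5 times.

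The replicate block gave 286 lower genes in blf13, and within each cultivar 193, with 116 changed in both, 29 with the reverse change and 40 lower in both; it moved no other count by over 1.5 times (nal1 1367 higher and 1245 lower with the block). Of the 393 genes changed in blf13 with the block within cultivars, 328 were among the 716. Replicate numbers of nal1 and Sebastian share only a number, as 2 of 6 libraries correlated best with their own number, against 6 of 6 for blf13 and Bonus.

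Without replicate 2 of both blf13 and Bonus, blf13 had 80 higher and 39 lower genes, the interaction 410, both mutants 25, opposite directions 18, higher in blf13 and lower in nal1 15, the reverse change 3, and lower in both 4, and the correlation of fold changes was 0.110 in place of −0.018. Leaving out 1 library at a time gave 111 to 579 higher and 72 to 1240 lower genes in blf13, 306 to 1436 higher and 341 to 1285 lower in nal1, 549 to 1541 for the interaction, 44 to 485 in both, 22 to 164 opposite, 16 to 42 higher in blf13 and lower in nal1, 6 to 122 with the reverse change, 12 to 252 lower in both, and a correlation of −0.152 to 0.161. The share of lower genes among changed genes over 100 CPM was 95.6% in blf13 and 86.9% in nal1, and 65.5% and 43.6% with loess normalization. It was 66.7% in blf13 without the replicate 2 pair, and 33.3% in nal1 against a fold of 1.5. With 119 and 77 changed genes at all levels there, the shares of 66.7% and 33.3% can rest on few genes. The p of the fullest run in nal1 was 0.0350 with loess normalization. The gene lists and the NARROW LEAF1 gene were not run, because no ID could be matched to a name. Depth limits the folds of genes absent from a genotype, which are lower bounds.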

Other observations

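Several of the genes with the largest changes also differed between the wild types. HORVU.MOREX.r3.2HG0203150, lowered in nal1, was at 9.27 CPM in Sebastian and at 0.0954 CPM in Bonus, close to the 0.147 CPM of nal1. HORVU.MOREX.r3.2HG0212120 was at 0.0224 CPM in nal1 and 3.91 CPM in Sebastian, but at 29.9 CPM in blf13 and 31.7 CPM in Bonus. HORVU.MOREX.r3.5HG0474210, at 53.1 CPM in Bonus and lost in blf13, had 0 CPM in Sebastian, and HORVU.MOREX.r3.3HG0310020 had 0 CPM in blf13, nal1 and Sebastian. The genes gained in nal1, HORVU.MOREX.r3.2HG0125800 and HORVU.MOREX.r3.2HG0125790, had no count in the 9 libraries of the other genotypes, and the gene gained in blf13, HORVU.MOREX.r3.5HG0444260, likewise had none outside blf13.

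A neighbouring pair on 5H, HORVU.MOREX.r3.5HG0436440 and HORVU.MOREX.r3.5HG0436450, singled out after their values were seen, had 0 CPM in blf13 and 4.34 and 5.23 CPM in Bonus, 4.36 and 5.53 CPM in nal1, and 3.50 and 4.99 CPM in Sebastian. The 19 genes changed 8-fold or more on 5H in blf13 ranked from 198 to 1948 among the 3570 tested genes of that chromosome.

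The 50 most expressed genes took 12.2% to 12.7% of the counts in blf13 and 13.2% to 13.5% in Bonus, and 11.7% to 12.1% in nal1 and 12.5% to 13.0% in Sebastian, so this share was lower in all 3 libraries of each mutant than in those of its wild type.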
